A study of Mus musculus with 2 samples.

How the data were processed

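RNA was isolated with a spin-column kit from sorted splenic germinal centre B cells, converted to Illumina TruSeq libraries and sequenced as paired reads of 50 bases on a HiSeq 2000, per the labels' protocols. Each of the 2 libraries was assigned to its group by the genotype label, Cbl-/-Cblb-/- or wild type, and each group holds 1 library. The submitters' processing notes name TopHat2 2.0.10, featureCounts, DESeq2 1.4.5 and the mouse build GRCm38, without saying which step each served. Annotation release, strand setting, handling of reads with several matches and the version of featureCounts were not given in the sources used here.

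The single deposited table lists 41214 genes, all with mouse Ensembl identifiers, although its name refers to a human liver line, and its value columns carry the titles of these 2 samples. The signal columns deposited by the authors are gene read counts normalized to library size, per the file headers. Every value was a whole multiple of the smallest positive value of its library within a tolerance of 0.001 read (100% of values in both libraries), so whole reads were recovered by dividing by that step. The steps correspond to size factors of 1.43066 and 0.698976 for the libraries labelled Cbl-/-Cblb-/- and wild type, which equal the median-of-ratios factors computed from the recovered reads. The authors' FPKM values, so named in the file headers, equalled the normalized reads divided by gene length and by 1 total common to both libraries. That relation was found from the values and is not stated in the headers. The FPKM values thus hold no information beyond the normalized reads and lengths and were used only in this check. Per the file headers, the deposited table also gives a base mean signal, a log2 fold change, its standard error, a test score and p-values from the authors' comparison of the 2 libraries. These p-values rest on no replicates and are quoted only as the content of the authors' deposited table.

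The comparison used the deposited normalized reads, as log2 of the value in the library labelled Cbl-/-Cblb-/- plus 1 over the value in the library labelled wild type plus 1, which understates differences of low genes. Genes with at least 100 normalized reads in the higher library were kept. The floor had been set in reads, and was applied to normalized reads because these are what the table holds. With 1 library per group no test was run and edgeR's quasi-likelihood test has no residual degrees of freedom, so no count test was run on the recovered reads and 0 genes are called. Ratios of single genes carry exact conditional 95% intervals, shares of reads Wilson 95% intervals, shares of genes exact Clopper-Pearson 95% intervals, and a count of 0 was replaced by 3 reads per library, equal to 2.10 and 4.29 normalized reads, for a lower bound on a fold. Reads carry no molecular identifiers, so the intervals of ratios and of shares of reads cover counting error only. Those of shares of genes treat genes as independent, which they are not. The library labelled Cbl-/-Cblb-/- (38223328 reads) detected 18402 genes and the library labelled wild type (26749540 reads) 16459.

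Named genes followed a rule set before the data were examined: Cbl and Cblb; the 12 highest and 12 lowest log2 ratios over the floor, leaving out immunoglobulin and T cell receptor segments, Gm and Rik names, clone names, small RNAs and pseudogenes; up to 4 members per gene list with the largest absolute ratio; and the regulators Bcl6, Prdm1, Irf4, Xbp1, Myc and Bach2. Some genes that the rule takes are not reported here. Other genes named, such as Alb, Fgb, Cd3e, Cd4, Cblc, Xist and the main Cr2 model, were chosen after their values were seen or as markers of file and sample identity. The 29 gene lists were fixed at the same time from general knowledge of germinal centre biology, and some genes are in more than 1 list. A list member counted as higher or lower from a 1.5-fold ratio, and the list median was placed among medians of 10000 random lists matched on mean expression in 20 bins, which describes these libraries and is no test.

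Gene positions, exon lengths, overlaps and GC content of the longest transcript came from GENCODE release M21 on GRCm38, which matched 10386 of the 10443 genes over the floor (99.5%). It is a newer annotation than the one behind the deposited lengths, and the ratio of its exon length to the deposited length is called model extension. Adjusted log2 ratios are residuals of a linear fit on log2 length, its square, GC content, its square and log2 model extension, an analysis added after the data were seen. Random lists matched also on length used 5 expression bins and 20 length bins. Genes matched to Cbl or Cblb were protein-coding genes within 0.5 of its log2 length and 1 of its log2 mean. The interval of the slope on length came from 200 resamplings of the genes.

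Alternatives were scaling to total reads, centring on the median, leaving immunoglobulin genes out of the scaling, pseudocounts of 0.5 and 5, floors of 20, 500 and none, leaving out immunoglobulin, Gm, Rik and pseudogene names, and a 1.5-fold threshold. TMM factors from edgeR 4.0.16 on the recovered reads and the adjustment were added later. Simulated reads were drawn with counting error only from the real means. The 200 changed genes had a mean of at least 200 normalized reads. Among 10095 genes over the floor, all 4-fold and 2.8-fold changes passed the 2-fold threshold and 0% of unchanged genes did. With a length slope of 0.6 added to the simulation (10355 genes), 92.7% of 4-fold and 90% of 2.8-fold changes passed. In that setting 14.8% of unchanged genes passed, and the slope was recovered as 0.601. The simulation held no other variation between libraries, so these rates do not carry over to the real ones. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.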

Results

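RNA was sequenced from germinal centre B cells, the activated B cells that divide, mutate their immunoglobulin genes and undergo selection in lymphoid organs. C57BL/6 mice received 1000000000 sheep red blood cells intravenously, and on day 10 splenic cells positive for B220, Fas and GL7 and negative for the plasma cell marker CD138 were sorted. The question put to the data was how gene expression in these cells differs when Cbl and Cblb, which encode E3 ubiquitin ligases that restrain antigen receptor signalling, are both deleted. There were 2 libraries, 1 labelled Cbl-/-Cblb-/- and 1 labelled wild type, so no difference between them has a replicate check. The library labelled Cbl-/-Cblb-/- held 38223328 reads assigned to genes and the library labelled wild type 26749540. Of 41214 genes in the deposited table, 19179 had a read in either library and 10443 reached a floor of 100 normalized reads in the higher one. Intervals of read ratios and of shares of reads are 95% intervals that cover counting error only. Those of slopes and of shares of genes are over genes, which are not independent replicates. The B cell gene Cd79a was abundant (30765 and 64212 normalized reads in the libraries labelled Cbl-/-Cblb-/- and wild type), whereas the hepatocyte genes Alb and Fgb had 0 reads in both.

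Neither targeted gene was lower in the library labelled Cbl-/-Cblb-/-. Cbl (ENSMUSG00000034342, chromosome 9, 44142976 to 44234049 on the minus strand of GRCm38) had 1693 reads in the library labelled Cbl-/-Cblb-/- and 118 in the library labelled wild type. After normalization this was 1183 against 169, a 7.01-fold higher value (5.81 to 8.52) in the library labelled as lacking the gene. Cblb (ENSMUSG00000022637, chromosome 16, 52031225 to 52208048 on the plus strand) had 4061 and 700 reads, or 2839 and 1001 after normalization, which was 2.83-fold higher (2.62 to 3.08) in the same library. The third family member, Cblc, was under the floor with 24 and 61 reads, 5.20-fold lower (3.20 to 8.73) in the library labelled Cbl-/-Cblb-/-. The values sum reads over each whole gene, and the exons removed in the mutant alleles were not given in the sources used here, so reads from remaining exons are included. Among 1308 protein-coding genes matched on length and mean expression, the log2 ratio of Cbl (2.80) lay at percentile 96.8, and that of Cblb (1.5) at percentile 75.2 among 1324 such genes. Without matching, among 9712 of the 9741 protein-coding genes over the floor, the percentiles were 97.4 and 83.4. Since neither gene was lower in the library labelled Cbl-/-Cblb-/-, every direction below is one between the labelled libraries and not between genotypes.

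Between the labelled libraries 2901 of the 10443 genes (27.8%) were at least 2-fold higher in the library labelled Cbl-/-Cblb-/- and 2430 (23.3%) at least 2-fold lower. The median log2 ratio was 0.15, with quartiles of -0.91 and 1.13. Scaling to total reads added 0.52 to the median and gave 4299 genes higher and 1475 lower. In the authors' deposited table, whose p-values rest on 1 library per genotype, 0 of 19179 genes had an adjusted p under 0.05 and the smallest adjusted p was 0.944. That table listed 511 genes with an unadjusted p under 0.05, 320 of them higher and 191 lower in the library labelled Cbl-/-Cblb-/-.

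The ratio between the libraries followed gene length. In 8 groups of about equal size, the median log2 ratio was -1.68 among genes of 36 to 1396 bases, 0.07 among genes of 2895 to 3652 bases and 1.35 among genes of 7609 to 84395 bases. In the shortest group 67.8% of genes were at least 2-fold lower in the library labelled Cbl-/-Cblb-/-, and in the longest group 62.5% were at least 2-fold higher. Each doubling of length went with 0.61 more on the log2 scale (0.58 to 0.66, resampling genes, which are not independent replicates). A fit on length, GC content and the extension of the gene model in a newer annotation took up 32.6% of the variance of the log2 ratios. With the fitted part removed, 1602 genes were at least 2-fold higher and 1888 lower among 10386 annotated genes, Cbl had an adjusted log2 ratio of 1.93 and Cblb one of 0.49. Ratios below are computed from the deposited normalized reads and not adjusted unless called so, and many of them are nearer 0 after adjustment.

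**Figure D1:**
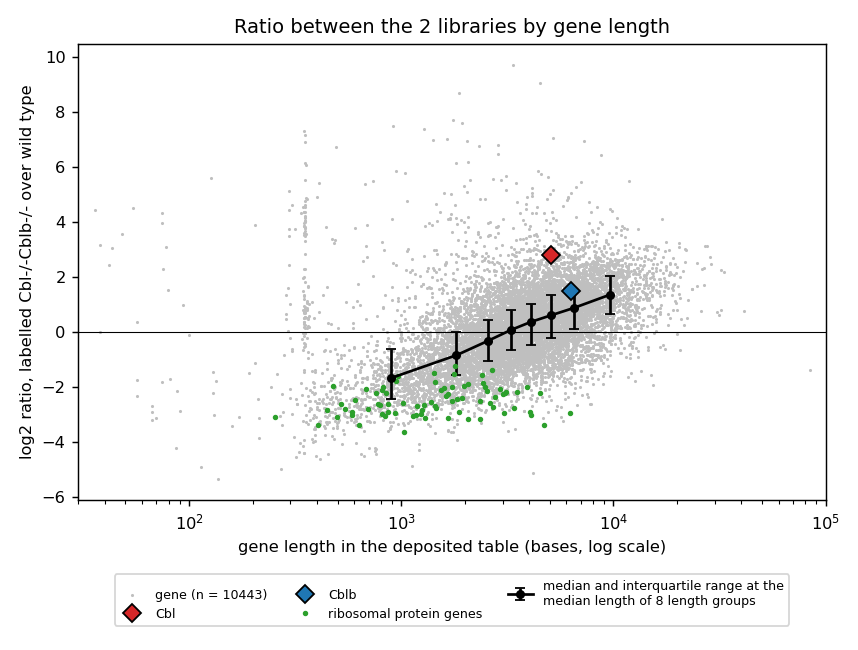
Log2 ratio of normalized reads in the library labelled Cbl-/-Cblb-/- over the library labelled wild type (y axis) against gene length in the deposited table (x axis, bases, log scale) for 10443 genes, 1 library per genotype. Black points and bars give the median and interquartile range of 8 length groups, which go from -1.68 in the shortest to 1.35 in the longest, with Cbl (2.80) and Cblb (1.5) as diamonds and ribosomal protein genes in green.

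The genes with the highest ratios were nearly missing from the library labelled wild type. Gprc5b, an orphan G protein-coupled receptor, had 762 reads against 0, at least 124-fold higher when the 0 is set to the floor of 3 reads in that library. Chml, a Rab escort protein gene, had 595 against 0 (at least 96.9-fold), Arhgap5 191 against 0 (at least 31.1-fold) and Zfp955a 182 against 0 (at least 29.6-fold). Egr3, an immediate early transcription factor gene, was 172-fold higher (47.5 to 1425) in the library labelled Cbl-/-Cblb-/-, with 705 reads against 2. Ccr6, a chemokine receptor gene of naive and memory B cells, was 151-fold higher (51.6 to 735), with 929 reads against 3. Similarly wide intervals applied to Lrrc8b (120-fold, 33.0 to 993), Atp7a (146-fold, 26.0 to 5789) and Slfn5 (77.9-fold, 21.4 to 646), which had 2, 1 and 2 reads in the library labelled wild type. Zfp146 was 77.2-fold higher (43.1 to 155) and Ulbp1, a ligand of the receptor NKG2D, 75.1-fold higher (40.7 to 157). A short gene model carrying the symbol Cr2 (ENSMUSG00000094924, 1044 bases) had 749 reads against 6, whereas the main Cr2 model (ENSMUSG00000026616) had 11210 against 3268 and a log2 ratio of 0.74 (adjusted -0.45), so the reads of the short model are uncertain in origin. Exons of another gene overlap Gprc5b, Chml and Slfn5 in the annotation, and the strand setting of the counting was not given, so their reads are uncertain in origin.

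At the other end, Cpne8 had 35 reads in the library labelled Cbl-/-Cblb-/- and 621 in the library labelled wild type, a log2 ratio of -5.13 (adjusted -5.72). Erdr1 (-4.89, adjusted -2.26), mt-Nd3 (-4.42, adjusted -4.06), Scand1 (-4.27, adjusted -1.58) and Hbb-bt (-4.23, adjusted -3.14) followed. Next were Hbb-bh1 (-4.06, adjusted -3.18), Yam1 (-3.94, adjusted -2.58), Rpl24 (-3.66, adjusted -2.73) and Atp5e, a subunit of ATP synthase (-3.65, adjusted -3.11). Proscos and Wdr89 both stood at -3.60 (adjusted -1.23 and -3.79) and Bola2 at -3.58 (adjusted -3.19). Apart from Cpne8 (4164 bases) and Wdr89 (3192 bases), these were short genes of 348 to 1831 bases. Ribosomal, globin and pseudoautosomal genes share sequence with paralogs or pseudogenes, and overlapping genes include Scand1, Yam1, Rpl24, Proscos and Bola2, so their counts are uncertain.

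Regulators of the germinal centre and plasma cell fates were detected in both libraries. Bcl6, the repressor that defines germinal centre B cells, had 13835 normalized reads in the library labelled Cbl-/-Cblb-/- and 7995 in the library labelled wild type (log2 ratio 0.79, adjusted 0.13). Bach2, which opposes plasma cell differentiation, had a ratio of 1.66 that was 0.39 after adjustment. Irf4 stood at 0.85 (adjusted 0.37) and Prdm1, which encodes the plasma cell regulator Blimp-1, at 1.09 (adjusted 0.37) from 349 and 80 reads. Xbp1, a transcription factor gene of the secretory programme, had a ratio of 0.16, adjusted to 0.44. Myc had a ratio of 0.47, adjusted to 0.93.

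Counts for gene lists are of members over the floor. For germinal centre B cell identity, 17 genes were over the floor, of which 3 were at least 1.5-fold higher and 2 at least 1.5-fold lower in the library labelled Cbl-/-Cblb-/-. The list median was -0.09, which turned positive when scaled to total reads and lay at percentile 71.6 of 10000 random lists matched on mean expression. Mybl1 (1.62, adjusted 0.48) and Stap1 (1.24, adjusted 0.30) were the highest and Nuggc (-1.38, adjusted -1.24) and Neil1 (-1.06, adjusted -0.14) the lowest. Of 19 plasma cell genes, 8 were higher and 6 lower, with a median of 0.44 at percentile 85.8, whereas after adjustment 3 were higher and 4 lower, with a median of 0.20. Within that list Trp53inp1, which is also induced by p53, stood at 2.43 (adjusted 1.15), while Fkbp11 (-2.46, adjusted -1.56), Cacna1s (-2.03) and the chaperone gene Mzb1 (-1.09, adjusted 0.05) were lower.

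Light zone and activation genes went in both directions, with 7 of 20 higher, 6 lower and a median of -0.03 that turned positive when scaled to total reads. It lay at percentile 33.6, or 90.2 with length matched too, and after adjustment 8 genes were higher and 3 lower. Beside Egr3, the NF-kappaB subunit gene Rel had 2753 against 196 normalized reads (14.0-fold higher, 11.8 to 16.8) and the cyclin gene Ccnd2 a log2 ratio of 2.48 (adjusted 1.62), whereas Bcl2a1b was at -2.14. Dark zone genes included 8 of 17 higher and 2 lower (adjusted 5 and 3), with a median of 0.31 (adjusted 0.27) at percentile 78.1, or 98.2 with length matched too. Polh, the error-prone polymerase of hypermutation, was 15.7-fold higher (13.9 to 17.9), Lig4 stood at 1.70 (adjusted 0.97), Plk1 at 1.47 (adjusted 2.32) and Hmmr at 1.44 (adjusted 0.49).

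Of 11 naive follicular B cell genes 8 were higher and 1 lower in the library labelled Cbl-/-Cblb-/- (5 and 0 after adjustment), and the median of 1.06 (adjusted 0.58) lay at percentile 96.6, or 99.3 with length matched too. Cd55 stood at 1.75 (adjusted 1.01), the egress receptor S1pr1 at 1.60 and Cd38, which mouse germinal centre B cells carry at low levels, at 1.57. Of 10 memory B cell genes 6 were higher and 1 lower (adjusted 6 and 0), with a median of 1.18 (adjusted 0.98) at percentile 95.9. Ccr6 led that list, followed by Nt5e (2.45, adjusted 1.32), and Cd38 is a member of both lists.

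Among 20 G2/M genes 9 were higher and 2 lower in the library labelled Cbl-/-Cblb-/- (5 and 3 after adjustment), with a median of 0.44 (adjusted 0.20) at percentile 95.5. Cenpf (2.5, adjusted 0.60), Kif11 (2.06, adjusted 1.13), Top2a (1.60, adjusted 0.12) and Plk1 (1.47, adjusted 2.32) had the highest ratios. Among 20 G1/S and replication genes 6 were higher and 3 lower (adjusted 5 and 3), with a median of 0.27 (adjusted 0.32) at percentile 88.7. Mcm4 stood at 2.23 (adjusted 1.92), Pola1 at 1.87 (adjusted 0.32) and Ccne2 at 1.45 (adjusted 0.74), against -1.18 (adjusted -1.99) for the thymidylate synthase gene Tyms. The 22 Myc target and ribosome biogenesis genes had 5 higher and 7 lower (adjusted 7 and 6), a median of 0.15 (adjusted 0.12) and percentile 70.4. Ppan (-1.77, adjusted -1.18), Fbl (-1.45, adjusted -0.90) and Nop56 (-1.40) were lower and the transferrin receptor gene Tfrc (1.39, adjusted 0.21) higher.

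In B cell receptor signalling, the pathway that Cbl proteins restrain, 8 of 20 genes were higher and 5 lower (adjusted 6 and 3). The median of 0.34 (adjusted 0.27) lay at percentile 98.1, where matched lists had a median of -0.51. Pik3ap1, the adaptor that links the receptor complex to PI3 kinase, was 11.6-fold higher (10.7 to 12.7) in the library labelled Cbl-/-Cblb-/-, and Malt1 stood at 2.01 (adjusted 0.49). Cd79b (-2.46, adjusted -1.46) and the inhibitory adaptor gene Dok3 (-1.90, adjusted -0.67) were lower. The Cbl family and its associated adaptors and ubiquitin ligases had 11 of 15 genes higher and 1 lower (adjusted 5 and 4), with a median of 1.06 at percentile 98.8. These genes are long, with a median of 7326 bases, and the list stood at percentile 63.2 once random lists were matched on length as well, with an adjusted median of -0.39. Ubash3b (3.24), Cbl, Nedd4 (2.44, adjusted 0.83) and Itch (1.90, adjusted 0.25) led it.

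Apoptosis regulators had 5 of 16 genes higher and 3 lower (adjusted 4 and 3), with a median of 0.22 (adjusted 0.08) at percentile 58.4, or 90.3 with length matched. Bcl2a1b (-2.14), Bax (-1.96, adjusted -0.04) and Bad (-1.94, adjusted -1.0) were lower. Unfolded protein response and secretion genes had 10 of 21 higher and 5 lower (adjusted 7 and 3), with a median of 0.54 (adjusted 0.19) at percentile 96.5, or 99.4 with length matched. Sel1l (1.75, adjusted 0.58), Atf6 (1.63, adjusted 0.26) and Hyou1 (1.51, adjusted 0.88) were higher and the stress-induced transcription factor gene Ddit3 (-2.58, adjusted -2.28) lower. For somatic hypermutation and class switching, 6 of 15 genes were higher and 3 lower (adjusted 3 and 4), with a median of 0.40 (adjusted -0.13) at percentile 71.5. Polh and Rif1 (3.0, adjusted 1.11) had the highest ratios in that list, Trp53bp1 had 1.72 (adjusted -0.13) and Lig4 1.70 (adjusted 0.97).

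Antigen presentation and costimulation genes had 2 of 16 higher and 9 lower in the library labelled Cbl-/-Cblb-/-, or 3 and 6 after adjustment. The median of -0.87 (adjusted -0.41) lay at percentile 16.6, or 63.8 with length matched too. Cd74, the invariant chain gene, had 207233 against 988927 normalized reads (-2.25, adjusted -1.10), and H2-Eb1 (-2.15, adjusted -1.37) and H2-DMa (-1.92, adjusted -1.17) were also lower. Cd274, which encodes the ligand PD-L1, was higher at 2.34. Receptors for T cell help had 3 of 14 genes higher and 1 lower (adjusted 4 and 1), with a median of 0.06 (adjusted 0.12) at percentile 60.4. That median turned negative when the log2 ratios were centred on the median of all genes. Slamf6 stood at 1.5 (adjusted 0.92), Cd84 at 1.22 (adjusted -0.01), Il21r at 0.94 (adjusted 1.48) and Il2rg at -1.26. Interferon-stimulated genes had 4 of 10 higher and 3 lower (adjusted 4 and 2), with a median of -0.12 at percentile 36.2. That median turned positive when scaled to total reads, with a floor of 20 (1.2) and after adjustment (0.49). Ifit2 (2.94), Mx1 (2.39) and Usp18 (1.23) were higher and Bst2 (-1.56, adjusted -0.21) lower, all on fewer than 1000 reads per library. Immediate early genes had 8 of 12 higher and 2 lower (adjusted 9 and 0), with a median of 0.70 (adjusted 1.08) at percentile 86.5, or 99.9 with length matched. Egr1 (1.93), Zfp36 (1.89) and Jun (1.42) were higher, against Jund (-1.82, adjusted 0.07).

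Ribosomal protein genes were lower in the library labelled Cbl-/-Cblb-/-. All 20 ribosomal protein genes listed were at least 1.5-fold lower, with 20 of 20 still so after adjustment. Their median of -2.30 (adjusted -1.61) lay at percentile 0.03, and at 0.01 when random lists were also matched on length. The adjustment and the matching used 1 deposited length per gene, with a median of 1752 bases here. The length of the transcripts sequenced was not known, so a part of the difference may still follow transcript length. Rpl13 (-3.16), Rps20 (-3.03), Rpl18 (-2.93) and Rpl8 (-2.62, adjusted -1.15) were the lowest of these 20. Over all ribosomal protein genes, 4.65% of reads in the library labelled Cbl-/-Cblb-/- and 18.8% in the library labelled wild type were of this class. Of 18 nuclear-encoded oxidative phosphorylation genes 12 were lower and 2 higher, with a median of -1.38 (adjusted -0.98) at percentile 0.54, or 18.6 with length matched. Cox5b (-2.63), Ndufa4 (-2.36), Cox7a2 (-2.23, adjusted -1.15) and Cox4i1 (-2.21, adjusted -0.93) were the lowest of these 18. Glycolysis genes had 5 of 14 higher and 7 lower (adjusted 3 and 5), with a median of -0.52 (adjusted 0.04) at percentile 33.5. Hk2 stood at 1.5, Pgk1 at 1.17, Gapdh at -1.48 and Aldoa at -1.10 (adjusted -0.37). Of 13 mRNAs encoded by the mitochondrial genome 10 were over the floor, with 7 higher and 2 lower (adjusted 7 and 1) and a median of 0.89 (adjusted 1.08) at percentile 99.4. Reads from the neighbouring and overlapping mt-Atp8 (3.89) and mt-Atp6 (3.12) cannot be separated with certainty, mt-Co1 stood at 1.91 and mt-Nd3 at -4.42.

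**Figure D2:**
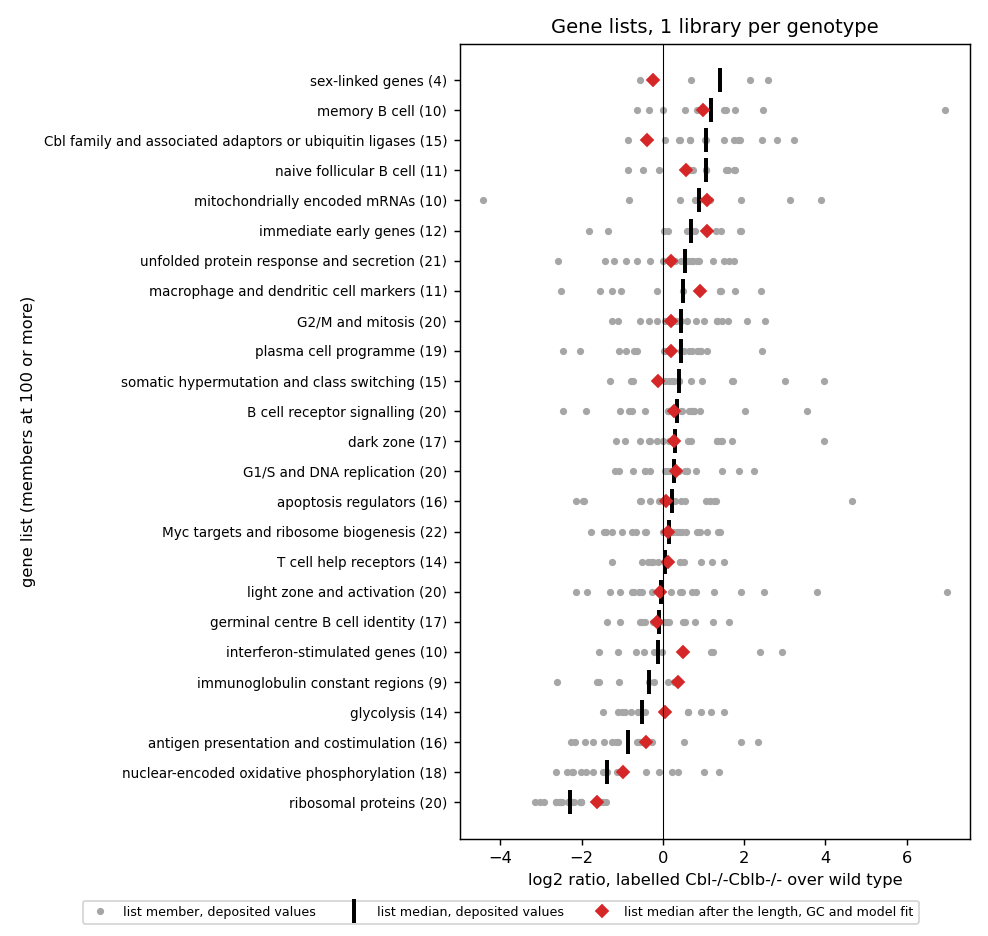
Log2 ratios (x axis, library labelled Cbl-/-Cblb-/- over library labelled wild type, 1 library per genotype) of the members of each gene list with at least 3 members over the floor (y axis, number of members in brackets). Grey points are members, black bars list medians, from -2.30 for ribosomal proteins to 1.42 for sex-linked genes, and red diamonds the medians after the fit on length, GC content and gene model extension.

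Immunoglobulin constant region genes had 0 of 9 genes higher and 4 lower (adjusted 3 and 3), with a median of -0.34 that turned positive when scaled to total reads and after adjustment (0.38). The list lay at percentile 49.7 on expression alone and at 99.97 with length matched. Igkc (-2.61, adjusted -1.64), Ighg1 (-1.62, adjusted -0.96), Iglc2 (-1.58, adjusted -0.62) and Ighe (-1.08, adjusted -0.24) were lower. Variable segments differed from the constant segments of the same chain. Summed over 110 heavy chain V segments there were 23695 reads in the library labelled Cbl-/-Cblb-/- and 757 in the library labelled wild type (log2 ratio 3.93), whereas the 7 heavy chain C segments had 247962 and 155213 (-0.36, turning positive when scaled to total reads). For the kappa chain the ratio was 0.38 over 98 V segments and -2.61 for the C segment, and for the lambda chain 0.05 and -1.58.

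**Figure D3:**
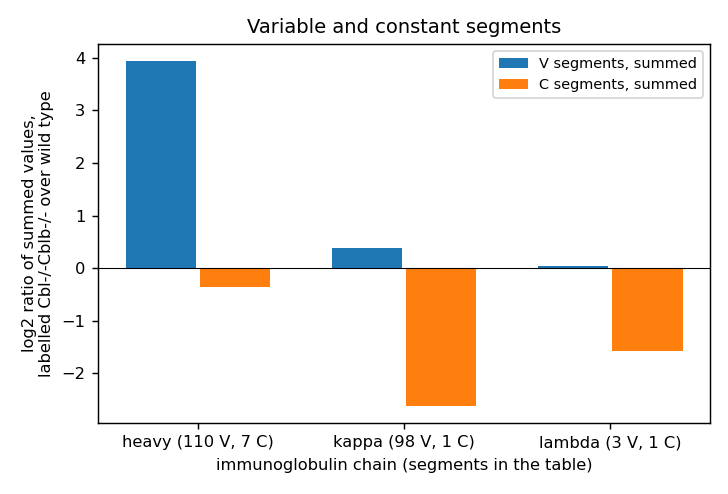
Log2 ratio of summed normalized reads (y axis, library labelled Cbl-/-Cblb-/- over library labelled wild type, 1 library per genotype) for variable (blue) and constant (orange) segments of each immunoglobulin chain (x axis, number of segments in brackets). Heavy chain V segments stand at 3.93 and C segments at -0.36, and the kappa values are 0.38 and -2.61.

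Of the markers of other cell types, those of neutrophils and most of those of T cells were under the floor. Among T cell markers only Cd2 (-1.57, adjusted -0.94) and Lck (-0.36, adjusted 0.12), which B cells also express, were over the floor, and Cd3e had 5 and 0 reads and Cd4 12 and 2. The highest neutrophil marker had 8.39 and 2.86 normalized reads in the respective libraries, and 0 such markers were over the floor. Erythroid and platelet markers over the floor were Hbb-bt and Car2 (0.91), and stromal and endothelial ones Acta2 (-1.63) and Pecam1 (0.74, adjusted 0.14). Macrophage and dendritic cell markers went up to 8455 normalized reads in the library labelled wild type. Of 11 over the floor, 5 were higher and 4 lower (adjusted 6 and 1), with a median of 0.49 (adjusted 0.92) at percentile 63.1, or 89.3 with length matched. Cst3 (-2.5, adjusted -1.17) was lower and Itgax (2.42) and Vcam1 (1.77, adjusted 0.93) higher, and C1qa was at -1.54 (adjusted 0.10). The Y-linked genes Uty (2.58, adjusted 0.66), Kdm5d (2.15, adjusted -0.05), Ddx3y (0.69, adjusted -0.44) and Eif2s3y (-0.55, adjusted -1.44) were present in both libraries, with a median of 1.42 (adjusted -0.25) at percentile 95.1, while Xist had 86 and 13 reads.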

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

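The TMM scaling, the adjustment for length, GC content and model extension, and the slope among genes with at least 1000 reads in both libraries were chosen after the data were seen. Directions below are between the labelled libraries, because neither Cbl nor Cblb was lower in the library labelled as lacking them. Pseudocounts of 0.5 and 5, TMM, and leaving immunoglobulin genes out of the scaling kept the direction of 128 of 128 named genes and of 25 of 25 list medians. These counts say little, since a pseudocount cannot change the direction of a gene. The median shift of the lists was only 0.0081 under TMM and 0.024 without immunoglobulin genes in the scaling. Scaling to total reads shifted the median of all genes from 0.15 to 0.67, which follows from its construction. It left 1475 genes at least 2-fold lower, Cbl at 3.32 and Cblb at 2.02, and list medians of 0.95 for plasma cell, 0.67 for Myc target, 0.79 for G1/S, 0.86 for B cell receptor signalling, 1.05 for unfolded protein response and -1.78 for ribosomal protein genes. Directions were kept by 127 of 128 named genes and 21 of 25 list medians under that scaling, and by 24 of 25 list medians under centring and under a floor of 20. Centring set the median of all genes to 0 and Cblb to 1.35. With no floor, 5484 genes were at least 2-fold higher and 4681 lower, since genes of few reads enter. The slope on length was 0.47 with a floor of 20, 0.81 with a floor of 500 and 0.73 among genes with at least 1000 reads in both libraries, and the cause was not tested. After the adjustment 1602 genes were at least 2-fold higher, the median of all genes was -0.058, Cbl stood at 1.93 and Cblb at 0.49. Under the adjustment 19 of 25 list medians kept their direction, and 6 reversed, namely the Cbl family (-0.39), hypermutation (-0.13), immunoglobulin constant regions (0.38), glycolysis (0.042), interferon-stimulated genes (0.49) and sex-linked genes (-0.25). The ribosomal protein median was -1.61. Among 116 named genes with a 2-fold ratio, 110 kept their direction and 6 reversed, namely Mzb1 (0.046), Cd84 (-0.0077), Trp53bp1 (-0.13), Jund (0.071), C1qa (0.10) and Kdm5d (-0.051), since the adjustment removes what length, GC content and model extension together predict. Of 25 list percentiles, 7 moved into or out of the middle 95% when random lists were matched on length too. No setting could leave out a library, and genes with 3 or fewer reads in a library, such as Egr3 and Ccr6, have folds known only to a wide interval.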

Other observations

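The explanations tested by the length slope, by immunoglobulin V against C segments and by the extended model of Cbl were tests chosen only after the result was seen. Immunoglobulin V segment use was similar in both libraries in its broad order but not in single segments. Across 105 heavy chain segments with reads, the read numbers correlated with a Spearman coefficient of 0.82, and across 95 kappa segments with 0.91, segments not being independent replicates. Ighv1-80 took 14.8% of the heavy chain V reads in the library labelled wild type (12.4 to 17.5, Wilson 95% interval for counting error) and 3.44% in the library labelled Cbl-/-Cblb-/- (3.22 to 3.68), on 757 and 23695 reads. Ighv1-9 did not differ detectably at this depth, with 7.40% (5.74 to 9.48) and 7.06% (6.74 to 7.39). Among kappa segments Igkv6-23 took 6.87% (6.50 to 7.26) and 2.01% (1.89 to 2.15), and Igkv8-30 1.73% (1.54 to 1.94) and 2.71% (2.56 to 2.86). These segments were chosen after their values were seen, and related V segments can share reads.

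Among heavy chain constant region reads, Ighm made up 71.4% in the library labelled Cbl-/-Cblb-/- and 51.1% in the library labelled wild type, and Ighg1 15.4% and 37.0%. These shares are not adjusted for length. The deposited length of Ighm (1486 bases) exceeds that of Ighg1 (974 bases), so the length trend may account for a part of the difference in Ighm. Shares of Ighg2b (1010 bases, 6.73% and 6.06%) and Ighg3 (992 bases, 4.15% and 4.10%) were close between the libraries. Both genes are about as long as Ighg1, so deposited length does not account for the lower Ighg1 share beside theirs. Ighg2c made up 1.97% and 1.2% and Ighe 0.23% and 0.38%. The small noncoding RNAs Rmrp, Rpph1 and Rn7sk, chosen after their values were seen, were lower in the library labelled Cbl-/-Cblb-/-, with log2 ratios of -5.01, -4.56 and -4.06.

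The log2 ratio was higher for longer genes, by 0.6137 per doubling of length. GC content as the whole source is argued against, because 0.8757 of the slope (0.860 to 0.890, resampling genes) was kept with GC content in the same fit. Low depth in the library labelled wild type is argued against as well, since the slope among genes with at least 1000 reads in both libraries was 1.197 times that over all genes. A candidate explanation that stays open is that reads of the library labelled wild type came mainly from the 3' ends of transcripts. The 5' V segments of the heavy chain stood 4.292 above its 3' C segments on the log2 scale, and those of the kappa chain 2.995 above. For the lambda chain, with 3 V segments, the difference was smaller (1.63). How such reads would arise was not tested, and the small noncoding RNAs Rmrp, Rpph1 and Rn7sk were not part of this comparison. A difference between the genotypes in the expression of long genes was not tested and cannot be excluded with 1 library each.

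Cbl and Cblb were higher in the library labelled as lacking them. Whether this follows from the length trend stays open: Cbl lay at percentile 96.79 and Cblb at percentile 75.23 of genes matched on length and mean expression, but both were within the middle 95% of protein-coding genes without matching too (97.4 and 83.4), and matching on expression alone put them at 97.6 and 83.7. The extension of the exons of Cbl from 5083 to 12345 bases in the newer annotation stays open likewise, at percentile 90.91 among 99 genes matched on it too. Exchanged labels cannot be told apart from correct ones here: the lower of the percentiles (75.23) shows no loss of Cblb in the library labelled wild type beyond the trend, and no percentile shows a loss of either gene in the library labelled Cbl-/-Cblb-/-. Alleles that still give transcripts counted over the rest of the gene stay open, as the counts are not given per exon.

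A set of 71 protein-coding genes had a log2 ratio of at least 4, among them Egr3, Ccr6 and Zfp146, so that few of their reads were in the library labelled wild type. Overlap of another gene with their last 500 exonic bases was 0.884 times as frequent as among matched genes (11.3%, 4.99 to 21, against 12.7%), an interval too wide to decide, although 63 of the 71 had none. Exons at least 1.5 times as long in the newer annotation were 3.265 times as frequent (56.3%, 44.0 to 68.1, against 17.3%). Reads of that library may thus lie in exons outside the counted models. Summed exon lengths do not show whether the added bases are at the 3' end, so a 3' position was not tested. The median GC content of the 71 genes, 45.37%, also lay below that of matched sets (47.3 to 51.2), so GC content stays open beside the extended models. The other 31 genes, with Ccr6 (1.14 times as long), Gprc5b (1.02) and Atp7a (1.0) among them, are not covered by that difference in models.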
